A study of Homo sapiens with 6 samples.

How the data were processed

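RNA was measured in 6 prostate cancer cell lines, each with 1 library: C4-2B, TaxR, CabR, DU145, DTXR and CTXR. Groups were taken from the sample labels, which name the parental lines, the docetaxel-resistant lines and the cabazitaxel-resistant lines derived from them. The title of the TaxR sample also carries the word old, which the labels do not explain. Per the labels' protocols, total RNA was isolated with TRIzol and stranded mRNA libraries were made with a directional kit. The submitters' processing notes name HISAT, StringTie and Cuffnorm and the build GRCh38, without versions. The gene annotation, the use of strand in counting and whether the 6 libraries were scaled together are not given in the sources used here.

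The authors deposited 1 table per library with FPKM, a fragment count scaled for transcript length and library size, for 60658 Ensembl gene identifiers, per the file headers. These are model-based estimates, so reads of paralogs, pseudogenes and overlapping genes were divided by the authors' software, and an exact 0 can be a failed estimate. FPKM are not counts, and no count model was fitted. Of the 60658 identifiers 56550 were matched to a gene symbol table and 57047 to GENCODE release 29, a GRCh38 annotation that gave names where the table had none, biotypes and coordinates. Read depth is unknown, so no counting interval or detection limit is given. The share of total FPKM on mitochondrial genes was 17.9% in C4-2B, 27.9% in TaxR, 26.5% in CabR, 40.7% in DU145, 40.2% in DTXR and 35.3% in CTXR. Across measured genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was 0.960 to 0.979 between libraries of the C4-2B lineage and 0.934 to 0.945 between those of the DU145 lineage.

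FPKM were used as deposited, on the log2(FPKM + 1) scale. Measured genes were the 17436 that reached 1 FPKM in at least 1 library, of which 13442 are protein-coding in the annotation. Each resistant subline was compared with its parent, and each cabazitaxel-resistant subline with the docetaxel-resistant subline it came from. Since each line has 1 library, a gene was called higher or lower by size, a log2 ratio of at least 1, with no p-value. Overlaps within a lineage were set beside the number expected of independent lists and beside 100 draws that shuffled each gene's 3 values among the lineage's libraries. Medians of 32 gene lists were ranked among 10000 random lists of the same size, each member drawn from the 201 genes nearest in mean log2(FPKM + 1). A list outside the 2.5 to 97.5 percentiles is said to stand apart, as a description of these libraries. For the mitochondrially encoded mRNAs, which are the most abundant genes, the random lists draw partly on the list's own members. The only replication in the design is that the selection was made in 2 parental lines, so limma was fitted to all 6 libraries with stage and lineage as terms, an intensity trend, empirical Bayes moderation and two-sided tests with Benjamini-Hochberg adjustment over the measured genes.

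Genes were named by a rule fixed, with the lists, the tests and the first set of alternative settings, before the data were examined. It takes ABCB1 first, then per lineage the 10 highest and 10 lowest genes in both sublines, the 5 highest and 5 lowest of each step from docetaxel to cabazitaxel resistance, up to 10 genes per direction past the size rule in all 4 sublines, and up to 4 members past the size rule per list. Genes with clone names only were not named, and some named by the rule are not reported here. Other members of the lists, the genes on chromosome 7 and the DU145-lineage genes seen in TaxR were named after their values were seen. That first set held other pseudocounts, filters on low values, rescalings of the libraries, variants of the limma fit and leaving out each library in turn. Protein-coding genes only, removal of the DU145-lineage share from TaxR, counts without TaxR and list medians with the libraries rescaled to the same total or upper quartile were added after seeing the data.

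The list percentile was tested on simulated data for TaxR against C4-2B, with 17436 genes and lists of 12 genes. Of 100 unchanged lists 3 fell outside the range, and 100 of 100 lists shifted by 1 on the log2 scale were above it. The unchanged lists were drawn at random from the measured genes, so few could fall outside by construction. They do not show how often lists of genes that vary together would do so. With the libraries rescaled by median-ratio size factors, 9 of 32 real lists lay outside in TaxR and 12 in CabR. There were 8 in DTXR and 15 in CTXR, each against its parent. The limma fit was tested on simulated data as given with its results. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.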

Results

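Messenger RNA was sequenced from 6 human prostate cancer cell lines, with 1 library per line. C4-2B is a castration-resistant, androgen receptor-positive line of the LNCaP family, and DU145 is a prostate carcinoma line that grows without androgen. TaxR was selected from C4-2B, and DTXR from DU145, under 5 nM docetaxel. CabR was then derived from TaxR, and CTXR from DTXR, under 5 nM cabazitaxel. Docetaxel and cabazitaxel are taxanes, drugs that stabilise microtubules, and per the labels the cells were untreated before harvest. The design asks how the transcriptome of taxane-resistant cells differs from that of the parental cells. Values are FPKM as deposited, and 17436 of 60658 listed genes reached 1 FPKM in at least 1 library. The total FPKM per library lay between 711766 and 818430, and 13418 to 14270 genes reached 1 FPKM in each. Read totals were not given in the sources used here, so the depth of the libraries is unknown. With 1 library per line no difference between a pair of lines has a replicate check, and none carries a p-value. A gene is called higher or lower when the log2 ratio of (FPKM + 1) is at least 1 in size, a scale that understates the change of genes with low FPKM.

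ABCB1, which encodes the drug efflux pump P-glycoprotein (gene ENSG00000085563, chromosome 7, 87503633 to 87713323, minus strand, GRCh38), was nearly silent in both parental lines and abundant in all 4 resistant sublines. Its FPKM was 0.259 in C4-2B, 526 in TaxR and 936 in CabR. In the other lineage it was 0.304 in DU145, 68.0 in DTXR and 94.2 in CTXR. The log2 ratios to the parent were 8.71 in TaxR, 9.54 in CabR, 5.73 in DTXR and 6.19 in CTXR. The step from the docetaxel-resistant to the cabazitaxel-resistant subline was smaller than the size rule, at 0.83 from TaxR to CabR and 0.46 from DTXR to CTXR. Of the other 8 measured efflux transporters, no member was higher in TaxR, CabR or CTXR, and ABCC2 alone was higher in DTXR (2.66 in DU145, 7.61 in DTXR, 1.58 in CTXR). ABCC4 was lower in TaxR and CabR (71.9, 18.7 and 27.4 FPKM in C4-2B, TaxR and CabR). ABCC1, the multidrug resistance protein MRP1, was lower in CabR alone (69.7 and 19.6 FPKM in C4-2B and CabR) and stood at log2 ratios of -0.96 to -0.98 in the other 3 sublines. ABCG2, the breast cancer resistance protein, was lower in DTXR and CTXR (4.75 in DU145 against 0.517 and 0.477), and ABCC3 in CTXR (45.9 and 21.4).

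**Figure D1:**
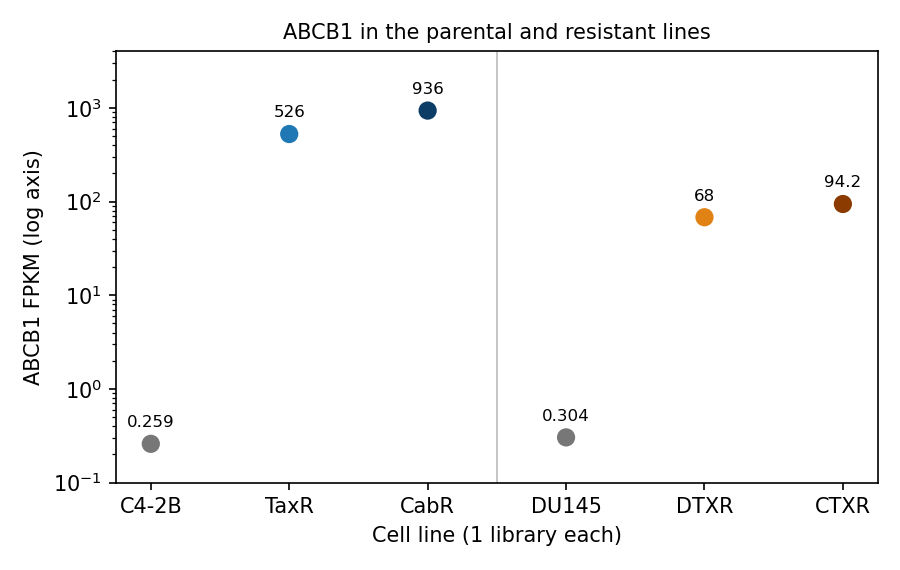
ABCB1 expression in FPKM on a log axis, 1 point per cell line and library, with the C4-2B lineage on the left of the grey line and the DU145 lineage on the right. The parental lines lie at 0.259 and 0.304, and the 4 resistant sublines between 68.0 and 936.

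Genes beside ABCB1 on chromosome 7 were higher in the resistant DU145 sublines. Of the 12 measured genes of a list of neighbours, 10 were higher in DTXR and 9 in CTXR, with median log2 ratios of 2.43 and 2.89, above all 10000 random lists of matched expression in both. The calcium-binding protein gene SRI had 40.8 FPKM in DU145, 492 in DTXR and 551 in CTXR. The replication kinase subunit DBF4 had 16.4, 169.6 and 119 FPKM, and the mitochondrial carrier SLC25A40 18.9, 164 and 156. GRM3, a glutamate receptor gene, was listed at 0 in DU145 and had 12.8 FPKM in DTXR, and it was higher in CTXR as well. In DTXR, 9 adjacent measured coding genes from DMTF1 to SRI, spanning 87152361 to 88226993, were past the size rule without a gap among measured genes. The coding gene ABCB4 also lies in this span but reached 1 FPKM in no library and was not counted. It was listed at 0 in DU145 and had 0.0393 FPKM in DTXR and 0.2145 in CTXR. The flanking genes ELAPOR2 (log2 ratio 0.77) and STEAP4 (0.18) were not past the rule. STEAP4 stayed under 1 FPKM in DU145, DTXR and CTXR, where the rule cannot be passed. GRM3 lies beyond ELAPOR2, outside this stretch, and had log2 ratios of 3.78 in DTXR and 4.47 in CTXR. In CTXR the stretch from DMTF1 to SRI was interrupted by RUNDC3B at 0.73. In the C4-2B lineage the list did not stand apart, with medians of 0.13 in TaxR and 0.01 in CabR (-0.02 and -0.04 with the libraries scaled to the same total). There the only neighbours past the rule were RUNDC3B (0.0679 FPKM in C4-2B, 11.4 in TaxR, 20.4 in CabR) and, in CabR, CROT (13.0 and 34.5 FPKM in C4-2B and CabR). RUNDC3B overlaps ABCB1 on the opposite strand, and the sources used here do not say whether strand was used in counting, so its values are uncertain.

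**Figure D2:**
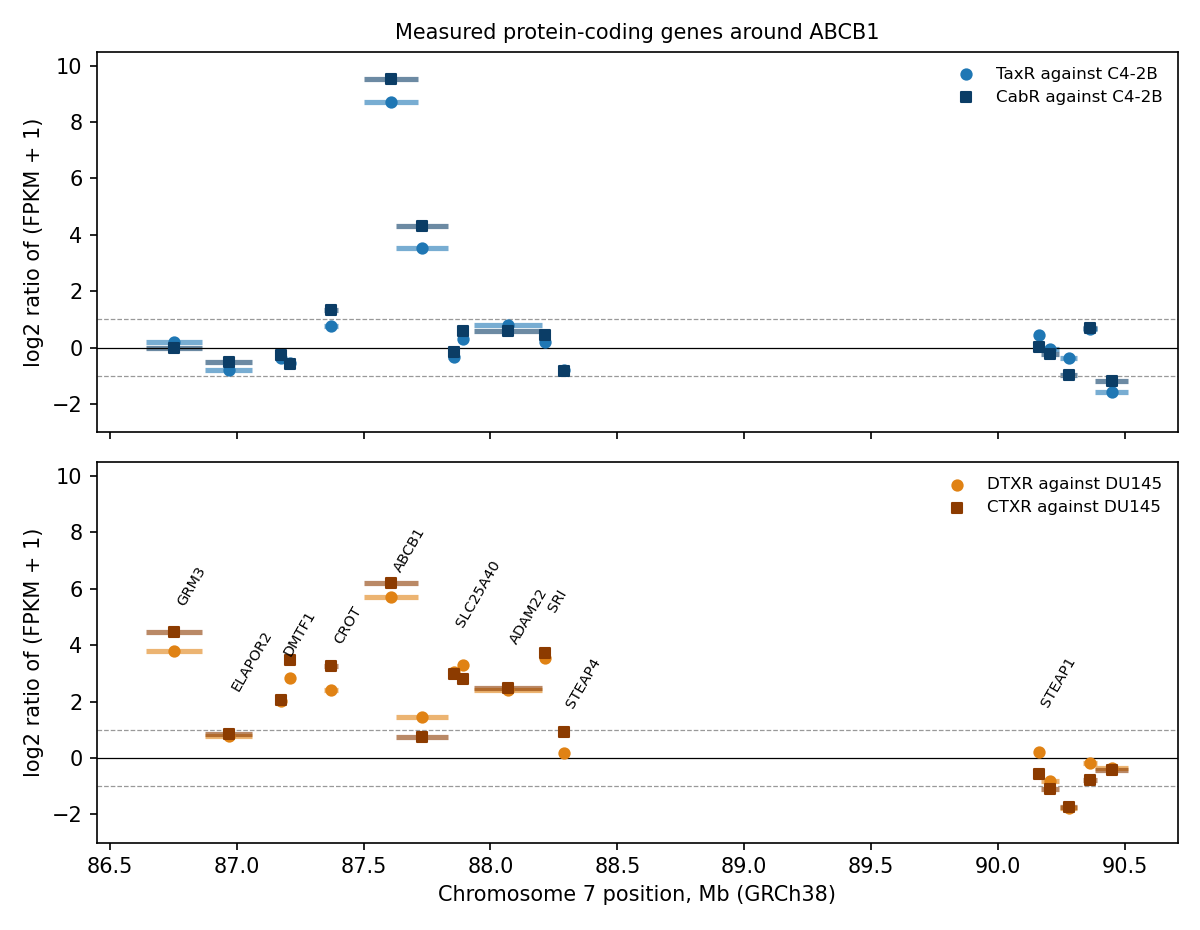
Log2 ratios of (FPKM + 1) to the parental line for measured protein-coding genes around ABCB1, against position on chromosome 7 in Mb (GRCh38), with the C4-2B lineage above and the DU145 lineage below. Bars span each gene, points mark its middle, and dashed lines mark the size rule. In DTXR and CTXR the genes from GRM3 to SRI lie above 0, with SRI at 3.56 and 3.72, whereas in TaxR and CabR SRI lies at 0.18 and 0.46.

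In the C4-2B lineage, genes of hypoxia and glycolysis were lower in both resistant sublines. Of 12 measured members, 9 were lower in TaxR and 10 in CabR, with medians of -1.50 and -1.86, below all 10000 random lists in both. The angiogenic factor VEGFA had 431 FPKM in C4-2B, 79.6 in TaxR and 43.2 in CabR. The glycolytic kinase PGK1 had 967, 273 and 260.4 FPKM, the glucose transporter SLC2A1 113, 38.6 and 31.4, and the prolyl hydroxylase EGLN3 26.7, 4.39 and 4.71. Genes of ER stress and the amino acid response followed the same direction, with 8 of 13 lower in TaxR and 5 in CabR (medians -1.07 and -0.69). DDIT4 had 823, 159 and 147 FPKM, and CHAC1 11.5, 0.744 and 2.71. NRF2 and glutathione genes had medians of -0.55 and -0.77, with 2 and 4 of 11 lower. HMOX1, the inducible haem oxygenase, had 47.8, 5.69 and 7.16 FPKM, and the cystine transporter SLC7A11 29.7, 3.99 and 4.47. Of 11 immediate early genes 4 were lower in TaxR and 6 in CabR (medians -0.50 and -1.04), among them EGR1 (5.96, 0.182 and 0.247 FPKM) and FOS (7.56, 0.678 and 0.589). The same single C4-2B library entered all of these ratios. Smaller negative medians were also seen in the DU145 lineage. For immediate early genes they were -0.44 in DTXR and -0.31 in CTXR, the latter inside the middle 95% of random lists. For ER stress genes they were -0.20 and -0.24, both inside it when the random lists were not matched on expression, and the latter also at the same upper quartile.

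Some metallothionein genes, whose products bind zinc and other metals, were among the lowest genes of TaxR and CabR. MT2A had 5793 FPKM in C4-2B, 109 in TaxR and 338 in CabR, and MT1X had 2881, 143 and 142. MT1B had 347 FPKM in C4-2B, was listed at 0 in TaxR and had 2.46 in CabR. Not all members were lower: MT1E was higher in TaxR (log2 ratio 1.35) and stood at 0.66 in CabR, and MT1A and MT1M did not pass the size rule in either. These genes are close paralogs, so how reads were divided among them is uncertain. The stress cytokine GDF15 had 1016, 84.7 and 57.2 FPKM, the glycoprotein hormone STC1 21.6, 1.32 and 0.726, and MAB21L4 51.4, 3.19 and 0.745. COLCA1, an antisense gene, had 12.8, 0.0266 and 0.504 FPKM. The short or repeated genes COX7CP2, U3 and RN7SL431P were listed at 0 in TaxR and CabR and had 29.7, 11.5 and 9.12 FPKM in C4-2B. Their reads can belong to near-identical copies.

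Genes higher in TaxR and CabR included fibronectin (FN1, an extracellular matrix protein), with 71.7 FPKM in C4-2B, 662 in TaxR and 855 in CabR. The vesicle protein SYT4 had 14.6, 121 and 94.4 FPKM, and GCH1, the first enzyme of tetrahydrobiopterin synthesis, 12.3, 89.7 and 66.7. CBLN2 had 0.884, 7.86 and 14.0 FPKM, SPAG16 0.124, 5.15 and 4.79, and the complement receptor CR1 was listed at 0 in C4-2B and had 5.30 and 4.24. SNORD3A (1.43, 28.2 and 48.6 FPKM) and RMRP also ranked among the 10 highest. RMRP is listed under 2 overlapping identifiers, of which 1 was higher in both sublines (0.0018, 61.0 and 6.95 FPKM) and the other lower in TaxR (12.9, 0.002 and 28.8), so no direction is given for it. Mitochondrially encoded mRNAs had medians of 0.85 in TaxR and 0.65 in CabR, with 5 and 4 of 13 higher, for example MT-ND2 with 2368, 8296 and 7839 FPKM. Mitochondrial genes held 17.9% of the total FPKM in C4-2B, 27.9% in TaxR and 26.5% in CabR. Tubulin isotypes, a list of alpha, beta and gamma tubulin genes, had small positive medians of 0.36 and 0.31 with no member higher, while TUBB3 was lower in CabR (22.1, 10.9 and 6.74 FPKM). Cancer/testis antigens had medians of 0.34 and 0.60, the former 0.18 and inside the middle 95% of random lists with the libraries scaled to the same total, and MAGEA10 was higher in CabR (23.8, 33.8 and 54.0 FPKM).

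Androgen receptor targets were lower mainly in CabR. Of 18 measured, 3 were lower in TaxR (median -0.18, inside the middle 95% of random lists) and 8 in CabR (median -0.73, below all 10000 random lists). KLK3, which encodes prostate-specific antigen, had 3567 FPKM in C4-2B, 3053 in TaxR and 841 in CabR. SLC45A3 had 155, 63.2 and 15.3 FPKM, TMPRSS2 344, 189 and 100.0, and the glucocorticoid and androgen response gene FKBP5 160, 144 and 61.3. KLK2 differed from these, with 515, 368 and 936 FPKM. MHC class I antigen presentation genes had a median of -0.72 in CabR, where 5 of 12 were lower, among them HLA-B (64.1, 41.5 and 17.4 FPKM) and HLA-C (161, 128 and 53.3). In TaxR the median was -0.23, inside the middle 95% of random lists. Of 18 epithelial junction genes 3 were lower in each subline, with a median of -0.39 in CabR and of -0.16 in TaxR, the latter inside the middle 95% of random lists. KRT19 and DSP were lower in both, CLDN4 in TaxR, and E-cadherin CDH1 in CabR (214, 183 and 94.5 FPKM).

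The size rule called 439 genes higher and 983 lower in TaxR against C4-2B, and 466 higher and 1081 lower in CabR against C4-2B. Both sublines shared 178 higher and 638 lower genes. Independent lists of these sizes would share 11.7 and 60.9, and shuffling each gene's 3 values among the 3 libraries, which keeps the shared parent, gave means of 125 and 304.5 over 100 draws, with ranges of 106 to 142 and 270 to 338. Part of the excess over independent lists can come from the shared parental library. TaxR also carried low levels of transcripts typical of the DU145 lineage. Of 10 DU145-side marker genes 6 were higher in TaxR (median 1.24) and none in CabR, with S100A6 listed at 0 in C4-2B and at 8.06 FPKM in TaxR and 762 in DU145. ANXA1, AXL, CAV1, CD44 and KRT7 stood at 1.59 to 3.16 FPKM in TaxR. UCHL1 (7.19 FPKM in TaxR, 570.3 in DU145) and DKK1 (1.39 and 384), also higher in TaxR than in C4-2B, were likewise far higher in DU145.

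In the DU145 lineage, interferon-stimulated genes were higher, most of all in CTXR. Of 17 measured, 5 were higher in DTXR and 10 in CTXR, with medians of 0.37 and 1.66, and the CTXR median lay above all 10000 random lists. ISG15, a ubiquitin-like interferon-induced protein, had 7.35 FPKM in DU145, 16.1 in DTXR and 56.4 in CTXR. IFI6 had 6.43, 3.59 and 43.8 FPKM, OASL 0.285, 0.183 and 6.94, and OAS3 0.822, 6.35 and 8.14. MX1 was higher in DTXR alone (0.422, 9.30 and 0.231). MHC class I genes had medians of 0.52 and 0.69, led by the immunoproteasome subunits PSMB8 (0.997, 25.4 and 25.9 FPKM) and PSMB9 (2.69, 11.7 and 25.3). B2M was higher in CTXR (454, 647 and 1526 FPKM). Cholesterol synthesis genes had medians of 0.72 and 0.40, with 4 of 12 higher in DTXR and 2 in CTXR, where random lists without expression matching put the median inside the middle 95%. FDFT1, squalene synthase, had 33.9, 78.8 and 99.0 FPKM, and HMGCS1 30.1, 129.7 and 36.8.

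Histone genes were lower in DTXR, where 9 of 10 measured members passed the size rule (median -1.71, below all 10000 random lists), and 2 did in CTXR (median -0.73). H1-2 had 384, 55.0 and 130.4 FPKM in DU145, DTXR and CTXR, and H2AC6 92.9, 13.1 and 24.2. Microtubule regulators had medians of -0.20 in DTXR and -0.43 in CTXR, and of -0.32 in TaxR and -0.02 in CabR, the last inside the middle 95% of random lists. The DTXR median also came inside it with a pseudocount of 0.1, with the same total or without expression matching. Members lower in both DU145 sublines were KIFC3 at 86.7, 36.9 and 30.9 FPKM and MAP7 at 5.62, 2.14 and 0.829, and STMN3 was higher in DTXR (log2 ratio 1.97). In CTXR the tubulin median was -0.29, which random lists without expression matching put inside the middle 95%, the proliferation median -0.35 with MKI67 lower (40.8 and 19.5 FPKM in DU145 and CTXR), and the NRF2 and glutathione median -0.41, with HMOX1 lower (157 and 50.8) and ALDH3A1 higher (log2 ratio 2.51). The hypoxia and glycolysis median was -0.16 in DTXR, inside the middle 95% of random lists, and -0.46 in CTXR, with 2 and 3 of 12 lower and ANKRD37 higher in DTXR (log2 ratio 1.16). Of NF-kB targets 2 were higher and 3 lower in DTXR and 3 higher and 3 lower in CTXR (medians 0.04, or -0.03 with the libraries scaled to the same upper quartile, and -0.47, the latter inside the middle 95% with a pseudocount of 0.1), ICAM1 being higher in both (1.48, 31.5 and 13.0 FPKM).

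The highest genes of both resistant DU145 sublines after ABCB1 included the antioxidant enzyme GPX1 (0.543 FPKM in DU145, 64.3 in DTXR, 71.9 in CTXR), the collagenase MMP1 (0.367, 36.7 and 95.6), the chemokine CXCL5 (0.0864, 36.3 and 28.1) and the interferon-induced membrane protein IFITM2 (6.61, 215 and 173). GPX1 is a polymorphic pseudogene in the annotation and had 186 to 265 FPKM in the C4-2B lineage. Its low value in the single DU145 library is therefore uncertain. The transcription cofactor LMO3 had 0.168, 20.6 and 89.6 FPKM, and the metallothionein MT1A 1.40, 80.1 and 37.7. TNFRSF6B, a decoy receptor, was near 0 in DU145, had 22.7 FPKM in CTXR and was higher in DTXR as well. GARIN2 was near 0 in DU145 and had 30.4 and 32.4, and ARMCX2 was listed at 0 and had 15.8 and 14.8. At the other end, the protease inhibitor TFPI2 had 258 FPKM in DU145, 16.9 in DTXR and 13.4 in CTXR. The WNT agonist RSPO3 had 33.6, 0.835 and 1.40 FPKM, the vitamin D hydroxylase CYP24A1 31.8, 1.71 and 1.21, the butyrylcholinesterase BCHE 64.4, 6.16 and 0.407, and CYP4F11 23.9, 0.105 and 1.54. CFAP299 had 15.6 FPKM in DU145 and was listed at 0 in both sublines. So were RNU2-37P, RPS28P7, RPS28P4 and PTGER4P2, which are small RNA or pseudogene copies with uncertain reads. In total 936 genes were higher and 890 lower in DTXR, and 1299 higher and 953 lower in CTXR. Both sublines shared 366 higher and 364 lower genes. Independent lists would share 69.7 and 48.6, and shuffled values gave means of 319 (276 to 359) and 437 (396 to 477). The shared higher genes were thus slightly more, and the shared lower genes fewer, than in each of the 100 shuffles.

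The cabazitaxel-resistant sublines were also compared with the docetaxel-resistant sublines they came from. CabR differed from TaxR at 305 higher and 321 lower genes. The organic cation transporter SLC22A3 had 0.174 FPKM in TaxR and 52.0 in CabR, the RNA-binding protein NOVA1 0.477 and 21.5, and the phospholipase PLA2G2A 0.162 and 16.0. Proliferation genes had a median of 0.53, above all 10000 random lists, with no member past the size rule. The median against C4-2B was 0.29, also outside the middle 95%, while CTXR against DTXR went the other way at -0.34, outside it as well. Androgen receptor targets had a median of -0.60, with KLK3, SLC45A3, FKBP5 and PMEPA1 lower and KLK2 higher. The androgen-inactivating glucuronosyltransferases UGT2B15 (2.23 and 8.95 FPKM) and UGT2B17 (2.98 and 10.2) and the steroid dehydrogenase HSD3B1 (0.378 and 3.39) were higher in CabR. The 5 lowest genes, MIR3648-1, MTATP8P1, TMEM167AP2, RPS27P4 and SNORD17, were listed at 0 in CabR and are short RNAs or pseudogenes, as is RNU2-2P among the highest. DU145-side markers had a median of -1.30 with 7 of 10 lower, the counterpart of their low levels in TaxR.

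CTXR differed from DTXR at 1271 higher and 915 lower genes, more than CabR from TaxR. The retinol dehydrogenase RDH10 had 195 FPKM in DU145, 10.7 in DTXR and 616 in CTXR, and the receptor phosphatase PTPRS 30.8, 0.261 and 42.6. The aspartic protease NAPSA had 1.28, 0.391 and 51.1 FPKM. In the other direction FHIT, a gene at a common fragile site, had 2.82, 348 and 1.79 FPKM, osteopontin (SPP1) 2.24, 122 and 0.644, and the transmembrane protein TENM3 0.0343, 17.4 and 0.031. The neuropeptide precursor VGF had 34.7, 38.9 and 0.853 FPKM. Interferon-stimulated genes had a median of 1.01, with 9 of 17 higher and MX1 lower, and histone genes a median of 0.87 with 3 of 10 higher. The keratin genes KRT7 (98.3, 490.4 and 30.1 FPKM) and KRT19 (60.8, 13.9 and 138) differed in opposite directions. SNORD3A, TMEM167AP2 and 1 of the RMRP identifiers were also among the 5 highest or lowest, with the same uncertainty as above.

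Few genes passed the size rule in the same direction in all 4 resistant sublines. There were 4 higher genes, where independent lineages would give 3.74, and 21 lower genes, where they would give 13.3. These expected numbers treat all measured genes as equally likely to be called. A gene can be lower only where its parent reaches 1 FPKM, so they are a rough guide and the excess of lower genes decides nothing. The higher genes were ABCB1, STEAP1B, the actin-binding thymosin TMSB4X and the acyl-CoA-binding protein DBI. TMSB4X had 26.9, 63.0 and 127 FPKM in C4-2B, TaxR and CabR and 120.0, 299 and 318 in DU145, DTXR and CTXR. DBI had 276, 663 and 580.1 FPKM and then 68.3, 138 and 163. STEAP1B log2 ratios lay between 1.29 and 1.65. Among the lower genes, the stress-response gene NDRG1 had 561, 89.1 and 57.3 FPKM in the C4-2B lineage and 25.7, 9.61 and 7.90 in the DU145 lineage. The heat shock gene HSPA6 had 6.80, 0.619 and 0.469 FPKM and then 8.41, 0.383 and 1.31. CYP4F11, RDM1, BEST1, CROCCP3, RN7SL431P and the antisense genes LIPE-AS1, HDAC4-AS1 and HILPDA-AS1 were the other 8 of the 10 whose weakest ratio was strongest. Without TaxR, 14 genes were higher and 35 lower in all of the other 3 sublines, counts that could not fall because fewer sublines had to pass. Antisense values are uncertain because the use of strand in counting was not stated.

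With lineage as a block, limma compared the 3 stages over the 2 lineages, so that the spread was the disagreement between lineages. At a Benjamini-Hochberg adjusted p of 0.05 it called 0 of 17436 genes in each contrast. At an unadjusted p under 0.05 there were 772 genes for docetaxel-resistant against parental, 835 for cabazitaxel-resistant against parental and 416 for cabazitaxel-resistant against docetaxel-resistant, where chance alone would give about 872. ABCB1 had a log2 difference of 7.22 (SE 0.74, higher in 2 of 2 lineages) in the docetaxel contrast, with a limma adjusted p of 0.141, and 7.86 (SE 0.74, higher in 2 of 2 lineages) in the cabazitaxel contrast, with a limma adjusted p of 0.163. Over the 32 fixed lists the counts adjusted over the list alone were 8, 12 and 2 list entries in the 3 contrasts, against 0 over all genes tested. ABCB1, NDRG1, HK2 and SLC2A1 were among these entries in both contrasts with the parental lines, ABCB1 higher and the others lower. Both contrasts use the same 2 parental libraries, so the recurrence is not a second check. No adjustment was made across the 32 lists. The 2 entries of the cabazitaxel against docetaxel contrast were the DU145-side markers ANXA1 and KRT7. ANXA1 was also among the 8 entries of the docetaxel contrast. The low levels of both genes in TaxR enter these differences and may come from mixed-in DU145-lineage material, as weighed below. On simulated data for the docetaxel contrast, with 17436 genes, the same fit recovered 16% of 50 genes changed by 1 on the log2 scale, 80.0% of 50 changed by 2, 98% of 50 changed by 4 and 100% of 50 changed by 6. It also called 16 unchanged genes, 9.82% of its 163 calls and so above the 5% aimed at. That simulation was too easy, since its spread varied less between genes than the real one (prior degrees of freedom fitted by limma 12.2 against 4.76). With variances drawn from the fitted prior (4.71) the recovery was 4%, 22%, 98% and 100%, and 3 of 115 calls were unchanged genes. The real ABCB1 difference was larger than any simulated one and was not called, so neither simulation gives the chance of calling that gene. The libraries of a lineage descend from each other and are not independent, while these p-values treat them as if they were.

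**Figure D3:**
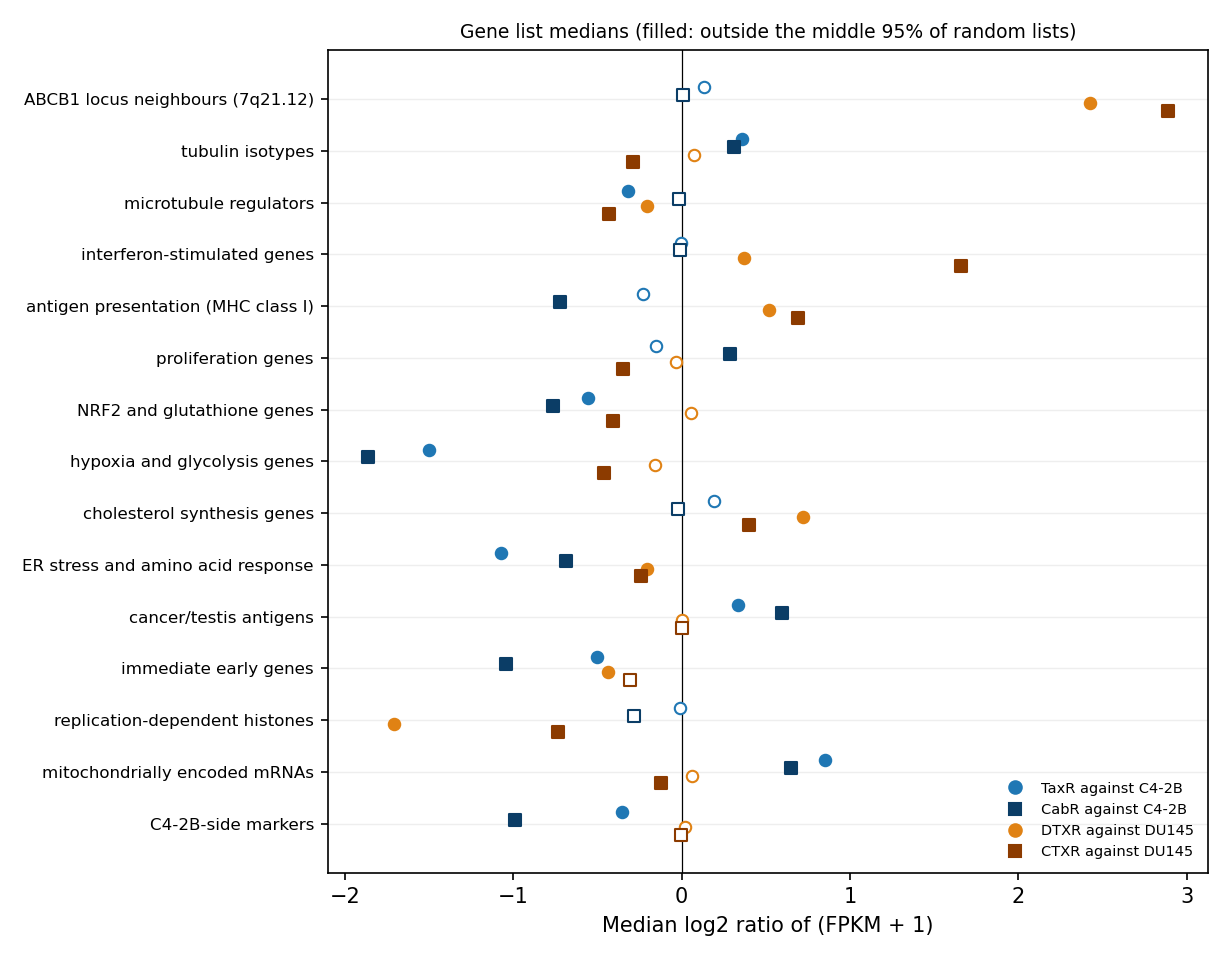
Median log2 ratio of (FPKM + 1) to the parental line for 15 gene lists that stood outside the middle 95% of matched random lists in at least 2 of 4 comparisons. Circles are docetaxel-resistant and squares cabazitaxel-resistant sublines, blue for the C4-2B and orange for the DU145 lineage, filled where the median lies outside that range. Hypoxia and glycolysis genes lie at -1.50 and -1.86 in TaxR and CabR, and interferon-stimulated genes at 1.66 in CTXR.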

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

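All tests of explanations in this part were chosen after the results were seen. A set of genes was singled out because its members moved one way in both sublines of one lineage and the opposite way in both sublines of the other. The difference between the lineages was not tested, since each line has 1 library. There were 5 genes higher in TaxR and CabR and lower in DTXR and CTXR, where independent lineages would give 3.72, and 13 genes lower in TaxR and CabR and higher in DTXR and CTXR, where 13.4 would be expected. The first set held IGFBP3, which encodes an insulin-like growth factor binding protein, at 13.0, 30.9 and 116 FPKM in C4-2B, TaxR and CabR and at 26.4, 6.32 and 0.863 in DU145, DTXR and CTXR. It also held RTN1, ICA1-AS1 and 2 antisense genes without an established symbol. The second set held the neuronal enolase ENO2 (67.3, 10.7 and 9.84 FPKM, then 8.19, 28.3 and 20.2), CD68 (6.81, 2.44 and 0.862, then 9.07, 82.4 and 25.8), KCNMA1 (39.1, 4.95 and 4.86, then 1.91, 5.56 and 26.3) and MLLT3. These were named after their values were seen.

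The first pattern weighed is the low level of DU145-lineage transcripts in TaxR. Among genes under 0.2 FPKM in C4-2B and CabR and at 20 FPKM or more in all 3 DU145-lineage libraries, 35 of 35 were above both relatives in TaxR, at a median of 1.18% of the DU145-lineage mean (quartiles 0.749% and 1.65%), whereas the mirrored rule in DU145, DTXR and CTXR gave 18 of 40, 7 of 34 and 17 of 39 genes above both relatives at medians of 0.027%, 0.0042% and 0.017%. With C4-2B or CabR in the place of TaxR, which is then a relative, only 4 genes each met the rule and 0 were above both. Mixed-in material of the DU145 lineage, as cells, RNA or index reads, may therefore account for it, but its origin within that lineage stays open: of 9 coding genes under 0.2 FPKM in C4-2B, CabR and parental DU145 and at 20 FPKM or more in DTXR or CTXR, 5 reached 0.1 FPKM in TaxR, near the floor, and the median share would bring only 1 of the 9 to 1 FPKM, too few to decide. A small share of TaxR cells that turned these genes on stays open, since 24 of the 35 genes lay within 2-fold of the median share and either account allows this, and a share of this size would add 0.640 FPKM to ABCB1 in TaxR, against the 526 measured.

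The second pattern is the lower level of hypoxia and glycolysis genes in TaxR and CabR. Rescaling the libraries does not remove it: over 3 rescalings and both sublines the median closest to 0 was -1.45, which argues against library scaling. The growth state of the single parental C4-2B culture, for example its density or medium, stays open together with a stable difference of the resistant sublines. C4-2B held the highest value of the 6 libraries for 11 of the 12 genes, and both accounts predict this, so they cannot be told apart with 1 parental library.

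The third pattern is the block of higher genes beside ABCB1 in DTXR and CTXR. In CTXR, 4 of 4 coding genes before the start of ABCB1 within the block, SLC25A40, DBF4, ADAM22 and SRI, were past the size rule. This argues against transcription running on past the end of ABCB1 as the account of these 4 genes. Their passing in DTXR was fixed in advance, since the block was drawn from the DTXR run. The next listed neighbour, STEAP4, lies outside the block and was past the rule in neither subline (log2 ratios 0.18 in DTXR and 0.93 in CTXR). It had 0.0275 FPKM in DU145, 0.162 in DTXR and 0.955 in CTXR. Values under 1 FPKM cannot pass the rule, so STEAP4 does not set the edge of the block. On the other side GRM3, beyond ELAPOR2, was past the rule in both sublines. A gain of the DNA segment and a regional activation of transcription without one both stay open and cannot be told apart, since either gives the count of at least 9 of 12 listed neighbours past the size rule in each subline, which is the pattern itself. That count took the place of a first test, the run of adjacent higher genes, which was 9 in DTXR and 4 in CTXR against at most 5 in 100 shuffled gene orders and left the question open too. The log2 ratios of the 9 neighbours inside the DTXR run, ABCB1 left out, differed by up to 2.09, which either account allows. The low end of that spread is RUNDC3B, whose values are uncertain, and DNA was not measured here.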

How the results depend on the processing

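Alternatives limited to protein-coding genes, with the DU145-lineage share taken off TaxR or counted without TaxR, and list medians rescaled to the same total or upper quartile, were chosen after the data were seen. Of the gene counts, 97 stayed within 1.5 times and 57 did not. Of the 97, 18 are counts with no filter on low values, which cannot change them because the size rule already needs 1 FPKM in a library. Of 960 list medians compared, 926 stayed on the same side of the percentile range, 22 moved inside the middle 95%, 12 moved out of it and 0 called medians changed sign. Scaling to the same total shifted every FPKM ratio of TaxR to C4-2B by the same -0.16 (log2), before 1 was added to FPKM. Leaving out each library in turn gave 0 limma calls in every contrast. Such a fit assumes that a lone library varies like the others. No paired analysis beyond the lineage term was possible because each line has 1 library. FPKM without read totals leave the limits set by depth unknown. The cause of the changes that follow was not tested, apart from those that test fewer genes or ask for fewer sublines by construction.

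With a pseudocount of 0.1, the higher and lower genes were 1228 and 1917 in TaxR, 1209 and 2051 in CabR, 1613 and 1832 in DTXR, and 2187 and 1810 in CTXR, each against its parent. They were 929 and 1145 in CabR against TaxR and 2288 and 1631 in CTXR against DTXR. Both sublines shared 600 higher and 1227 lower genes in the C4-2B lineage and 845 and 768 in the DU145 lineage, and all 4 shared 57 and 98. ABCB1 log2 ratios were 10.52, 11.35, 7.40 and 7.87 in TaxR, CabR, DTXR and CTXR. limma called 1 gene for cabazitaxel-resistant against parental and 2 against docetaxel-resistant. With a pseudocount of 0.5, 700 genes were higher in TaxR, 708 in CabR and 295 in both, CabR against TaxR had 486 higher and 534 lower, and all 4 sublines shared 10 higher and 41 lower.

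With a mean of 5 FPKM or more, the higher and lower genes were 178 and 402 in TaxR, 204 and 484 in CabR, 441 and 345 in DTXR, and 594 and 454 in CTXR. They were 97 and 108 in CabR against TaxR and 539 and 457 in CTXR against DTXR. Both sublines shared 95 and 265 in the C4-2B lineage and 187 and 121 in the DU145 lineage, and all 4 shared 7 lower genes. With protein-coding genes only, 252 were higher and 551 lower in TaxR, 295 and 670 in CabR, and 145 and 162 in CabR against TaxR. The lower genes were 537 in DTXR, 598 in CTXR, 369 in both C4-2B sublines, 184 in both DU145 sublines and 8 in all 4. Scaled to the same total, 1542 genes were lower in TaxR and 39 in all 4 sublines. Median-ratio size factors gave ABCB1 log2 ratios of 8.68, 9.49, 5.74 and 6.25. Without TaxR, the remaining 3 sublines shared 14 higher and 35 lower genes, which could only stay or rise. With no filter on low values limma called 941, 1148 and 641 genes in the docetaxel, cabazitaxel and cabazitaxel against docetaxel contrasts, but over 50% of the residual variances were then exactly 0, which makes that fit unreliable.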

Other observations

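The scan for runs of neighbouring genes and the choice of the genes named in this part were made after the data were seen. Several lists gave few called members. Of 13 measured apoptosis regulators, BBC3 was lower in TaxR and CabR (9.03, 2.25 and 3.01 FPKM in C4-2B, TaxR and CabR) and BCL2L11, a pro-apoptotic BH3 protein, was higher in CTXR (log2 ratio 1.23). Of 12 p53 targets, GDF15 was lower in TaxR and CabR, and PHLDA3 was higher in TaxR, DTXR and CTXR. Homologous recombination genes had medians between -0.17 and 0.13 in the 4 comparisons with a parent, with CHEK2 higher (24.3 and 55.8 FPKM in DU145 and CTXR) and XRCC2 lower (14.3 and 5.39) in CTXR, FANCD2 lower in TaxR (log2 ratio -1.18) and BARD1 higher in CabR (1.08). Ribosomal protein genes had medians between -0.07 and 0.22, with 2 of 20 higher in CTXR. Of 10 WNT pathway genes, FZD7 was lower in TaxR and CabR, and DKK1 was higher in TaxR and lower in DTXR and CTXR (384, 127 and 141 FPKM in DU145, DTXR and CTXR). RNF43 was higher in DTXR (log2 ratio 1.57), and in CTXR SFRP1 (2.11) and NOTUM (1.17) were higher and LEF1 (-1.12) lower. Neuroendocrine markers had 5 measured members and medians inside the middle 95% of random lists in each of the 4 comparisons, except that a pseudocount of 0.1 took the CTXR median from 0.38 to 0.86 and out of it. The mesenchymal genes went both ways in the DU145 lineage, with 3 of 12 higher and 3 lower in DTXR and 1 higher and 2 lower in CTXR. S100A4 was lower in both sublines (109, 2.61 and 26.8 FPKM) and TGFBI higher in both (log2 ratio 1.40 in CTXR). The 7 measured basal genes had medians between -0.13 and 0.32 in the 4 comparisons with a parent. Markers of other cell types were mostly absent: 1 of 11 leukocyte, 4 of 10 fibroblast and 3 of 8 endothelial markers were measured. The median of the 4 fibroblast markers was 1.11 in CTXR, inside the middle 95% of random lists with a pseudocount of 0.1, where COL3A1 (1.31 and 6.85 FPKM in DU145 and CTXR) and COL1A2 (0.0762 and 2.25) were higher and COL1A1 (log2 ratio 0.63) and PDGFRB (0.02) were not. C4-2B-side markers, most of which are also among the androgen receptor targets, had medians of -0.35 in TaxR, inside the middle 95% under 4 alternative settings, and -0.99 in CabR.

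CLDN7 had 3.08 FPKM in DU145, 25.6 in DTXR and 35.5 in CTXR, and CLDN4 had 2.67, 0.857 and 17.7, the DTXR value not past the size rule. The epithelial junction list they belong to stayed inside the middle 95% of random lists in both sublines, with medians of -0.13 in DTXR, or -0.21 and outside it with a pseudocount of 0.1, and 0.24 in CTXR. CDH1 stayed under 1 FPKM in these 3 libraries. FHIT, SPP1, TENM3 and PTPRS each differed by over 10-fold between DTXR and both its parent and its descendant.

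Other runs of neighbouring genes stood apart. Medians of 11 adjacent measured coding genes were compared with the most extreme median in 100 shuffled gene orders. In DTXR a segment of chromosome 4 from 174283677 to 183448198 (GRCh38) had 9 of 13 genes higher, with a most extreme window median of 1.57 against 1.47 in the shuffles, and included VEGFC, NEIL3 and TENM3. A segment of chromosome 19 from 617224 to 1021179 had 9 of 18 genes lower in DTXR, among them FSTL3, PALM and MISP (window median -1.81). In CTXR a zinc finger gene cluster on chromosome 19 from 52113091 to 53430413 had 14 of 25 genes lower and 0 higher (window median -1.70), and a segment of chromosome 2 from 223957404 to 230225729 had 8 of 18 lower and 3 higher, with COL4A3, COL4A4, MFF and AGFG1 among the lower genes (window median -1.75). A segment of chromosome 8 from 24440930 to 27311319 had 7 of 12 higher in CTXR (1.67 against 1.57 in the shuffles). In CabR 4 of 12 genes on chromosome 7 from 45574140 to 50793462, including IGFBP3 and GRB10, were higher (0.83 against 0.80). The remaining regions were the metallothionein cluster on chromosome 16 in TaxR and CabR, the histone clusters on chromosome 1 in DTXR and CTXR and on chromosome 6 in DTXR, and the block around ABCB1 in DTXR and CTXR.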
